A study of Mus musculus with 12 samples.

How the data were processed

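Liver RNA of AhCre mice was hybridized to 1 Affymetrix-type array per sample, 12 arrays in 4 groups of 3. Per the labels, total RNA was extracted with Trizol and RNeasy and labelled with an Enzo BioArray kit; the array type, scanner software, detection calls and any filter are not given in the sources used here. The deposited values are in the unit score: within each array the authors took the log of the signal, subtracted the array's mean and divided by the array's SD, so a difference of 1 is 1 array SD and not a log2 fold. Over the deposited probe sets the scores had mean -0.0219 and SD 1.051 in WT replicate 3, and -0.005 and 1.007 in ApcMyc replicate 2. The mean and SD used were therefore not exactly those of the deposited probe sets. The 6 deposited SAM lists likewise hold a score per probe set, the SAM statistic, and other columns with a ratio of scores made by the authors with SAM, which was not used as a fold. The lowest scores of each array step as logs of a grid of 0.1 with a floor of 1, which gave each array's constants in 20 iterations and so the linear signals; 100.0% of signals below 1000 lay within 0.01 of the grid in every array.

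The recovered signals of all 32176 deposited probe sets were quantile normalized, 16 was added and log2 taken. The 61 control probe sets were left out of the tests, and 32115 were tested, each on its own. A model with 4 group means over the 12 arrays was fitted with limma 3.58.1 in R 4.3.3, with moderated variances, for 6 comparisons: Apc minus WT, ApcMyc minus Myc, Myc minus WT, ApcMyc minus Apc, ApcMyc minus WT, and the difference between the first pair (the interaction). P-values are two-sided and were adjusted by Benjamini and Hochberg within each comparison, with calls at an adjusted p under 0.05. The plan made before the data were examined fixed the groups, gene lists and tests, and assumed log2 or linear values and 1 probe set per gene throughout. Since the deposited values are scores and most probe sets carry no name, signals were recovered first and every probe set was tested, which departs from that plan; the scores as they are and 1 probe set per named gene were run as alternatives. Other work used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

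Gene names were taken from the 3 looser lists the authors deposited, which pair probe sets with symbols, and were matched to a mouse RefSeq gene table of assembly GRCm38.p6, used for names alone. The lists hold 2975 probe sets: 24 controls, 230 without a symbol, 204 with several symbols and 2517 with 1 symbol. Of the last, 1978 symbols were as in the table, 376 were updated through synonyms and 163 were not matched. They stand for 2176 genes, of which 269 had 2 or more probe sets; the brightest probe set stood for a gene. The other 29598 tested probe sets carry no name here and enter counts only.

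The named genes follow a rule of that plan: per comparison the 10 named genes with the largest called rise and the 10 with the largest called fall, with Myc, Glul, Axin2, Lgr5, Cyp2f2 and Ccnd1 in every comparison, and up to 4 members with the smallest p of each of 30 gene lists of pathways and cell types. Some genes that the rule selects are not reported here. Of the 30 lists, 25 had at least 3 measured members and were tested for a shift against the other named genes with camera of limma at a preset correlation of 0.01, 150 tests adjusted together, beside fry and camera with an estimated correlation. A shift is described by the median of its members; in every called shift median, mean and test had the same sign. With an estimated correlation only the pericentral shifts in Apc against WT and in ApcMyc against Myc held.

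The slope of one response on the other came from a least-squares line through the origin over probe sets, with a jackknife SE over the arrays. For the interaction, the count of calls was compared with counts after random reassignment of the residuals of the fit without an interaction, 100 assignments with the real one. On simulated data with 200 of 32115 probe sets changed, the fit of Apc against WT recovered 0% at a log2 change of 0.5, 43% at 1 and 97% at 2, with 0, 4 and 9 false calls; the interaction recovered 0%, 0% and 83%, with 0, 0 and 15. With so few changed probe sets the adjusted threshold is stricter than in the real comparisons, so these shares do not carry over to them. In Apc against WT 4996 probe sets were called, of which 1277 rises and 965 falls were at least 2-fold. Over all probe sets the numbers of the replicates showed no pairing of WT with Apc arrays: residual correlations of arrays with the same number were 0.0627, 0.00557 and -0.0122. The 18S rRNA control, though, was highest in replicate 1 of both, at 9.699 in Apc and 9.683 in WT. It was 8.015 to 8.468 in the other WT and Apc arrays, so a feature shared by the replicate 1 arrays is not excluded.

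Alternatives were another array scaling, other pseudocounts (1 and 64), an intensity trend in the variance prior, only the groups compared, a filter that removed the lower part of the probe sets by mean, other handling of several probe sets per gene, the deposited scores, a replicate block and leaving out each array in turn. Most changed 1 choice, but the block was fitted on WT and Apc arrays alone, and both forms of the scores also leave out the recovery of signals and the added 16, the scores as they are the quantile normalization too. The scores as they are, the slope on other scales, and the poly-A, 18S and transferrin receptor controls were added after the values were seen. Control probe sets were compared between title styles by exact two-sided permutation tests of 6 arrays against 6, whose smallest possible p is 0.00216, 12 tests adjusted together.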

Results

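Liver RNA from mice carrying AhCre, a Cre recombinase gene switched on by beta-naphthoflavone, was measured on 12 arrays in 4 groups of 3: no floxed gene (WT), Apc deleted (Apc), Myc deleted (Myc) and both deleted (ApcMyc). Per the labels the inducer was injected 3 times in 1 day at 80 mg/kg and livers were collected on day 4. Apc restrains beta-catenin, the effector of Wnt signalling, and Myc is a transcription factor and a Wnt target. The design asks what Apc loss changes in the liver, and how far that response needs Myc. The deposited values cover 32176 probe sets per array, which may not be all that the array holds. Over these, the median signal ran from 35.4 to 53.7 in the WT and Apc arrays and from 59.5 to 106.9 in the Myc and ApcMyc arrays. It was 59.5 to 78.9 in the Myc arrays and 86.5 to 106.9 in the ApcMyc arrays, so array brightness differed along with Apc loss there. Between 79 and 532 probe sets per array sat at the lowest signal, and the number of arrays limits the precision of every value. Each title carries an identifier of its own, though the labels do not state that the arrays came from separate animals, so the p-values measure the spread between these samples, which may be technical replicates. The titles have 2 styles, WT and Apc in one and Myc and ApcMyc in the other, so a difference between title styles and Myc deletion cannot be told apart; the comparisons of Apc with WT and of ApcMyc with Myc lie within a style.

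The controls of the arrays also differed between the title styles: the labelling control dap was higher by 3.88 (log2) in the WT and Apc arrays (exact two-sided permutation p = 0.00216, n = 6 per style).

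**Figure D1:**
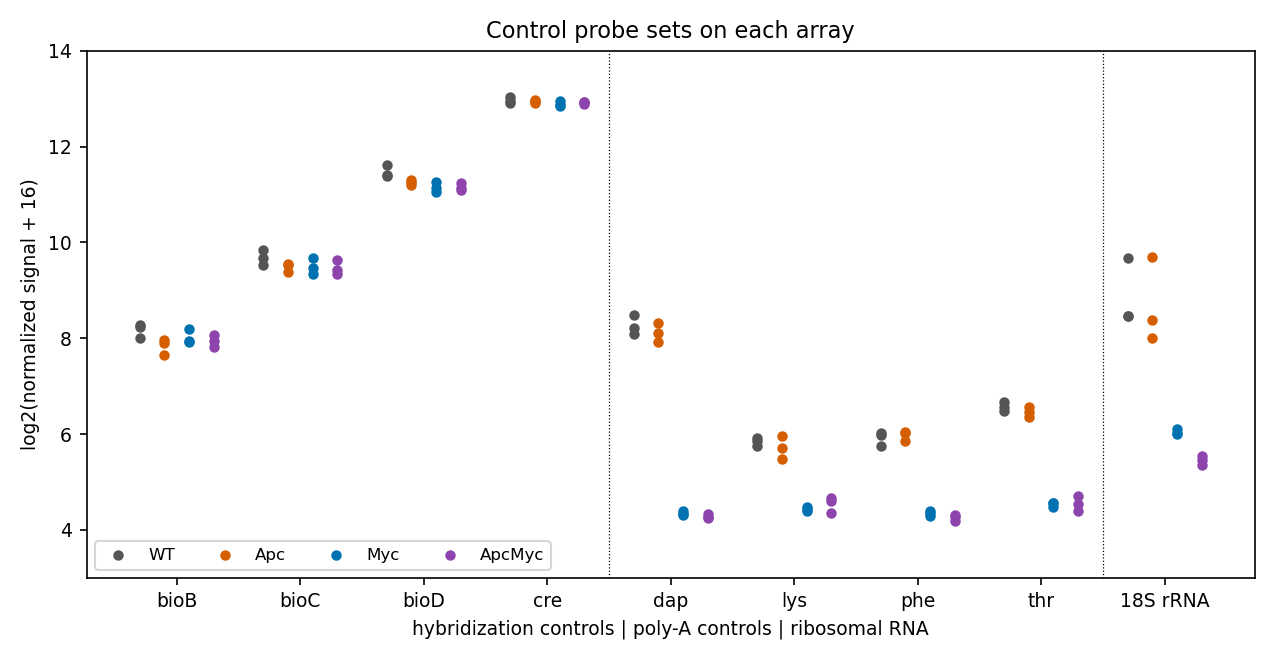
Log2 of the normalized signal plus 16 of 8 spiked control RNAs and of 18S rRNA in each array, by group (3 arrays each). The labelling control dap stands at 8.19 on average in the WT and Apc arrays and at 4.31 in the Myc and ApcMyc arrays, and the hybridization control bioB at 8.01 and 7.98.

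Values are log2 of the normalized signal plus 16, which understates folds of genes with low signal, and a change is called at an adjusted p under 0.05. Gene names come only from lists that the authors chose on these samples for Apc against WT, ApcMyc against Apc and ApcMyc against WT, so the counts of named genes are not independent evidence of direction. They name 2176 genes, and the Apc gene itself is not among them. The list of ApcMyc against WT holds 2871 of the 2975 probe sets, so most named genes were chosen for a change in that comparison. The gene lists fixed in advance are measured only in part, such as 18 of 41 periportal, 18 of 40 pericentral, 12 of 25 Wnt target and 24 of 46 cell cycle genes. Others had fewer, with 6 of 21 macrophage, 8 of 25 endothelial, 4 of 20 T and NK cell and 4 of 64 ribosome biogenesis and Myc target genes. A gene counts as measured only if it is named, so other members may be among the unnamed probe sets. Members of close families, such as Mup3, Ugt2b38, Cyp2c39 and Gstm2, may be measured together with their relatives, so their identity is uncertain. Along the main axis of variation, 32.4% of the variance, the Apc-deleted arrays separated from the others, and the next, 24.1%, separated the title styles. Correlations between arrays of a group, across probe sets, were between 0.957 and 0.981.

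With Apc deleted and Myc intact, Myc rose 6.64-fold, from 6.07 ± 0.678 in WT to 8.80 ± 0.258 in Apc (log2, mean ± SD, n = 3; difference 2.73, adjusted p = 5.85e-05). Genes that normally mark the hepatocytes around the central vein rose, and genes of the hepatocytes around the portal vein fell. Glul, the glutamine synthetase of the last cells before the central vein, rose by 2.41 (SE 0.141, adjusted p = 7.01e-07), and Rhbg, an ammonium transporter, rose 17.7-fold (4.15, SE 0.173, adjusted p = 7.6e-08). Hal, which starts histidine breakdown, was 88.7-fold lower (-6.47, SE 0.398, adjusted p = 9.13e-07), and Gls2, the liver glutaminase, was 84.3-fold lower (-6.40, SE 0.42, adjusted p = 1.55e-06). Of the other genes with the largest rises, Cyp4a14, a fatty acid hydroxylase, rose by 6.01, Afp, a fetal liver protein, by 5.55, Ly6d by 5.23, Plat, a plasminogen activator, by 5.17, Acot3 by 4.69, D17H6S56E-5 by 4.35, Slc22a3, a cation transporter, by 4.32, Akr1b7 by 4.29 and Cdkn1a, a cell cycle inhibitor, by 4.08. The other large falls were Hsd3b5 (-6.65), a steroid enzyme of male liver, Sds (-5.89), which breaks down serine, Dio1 (-5.82), the deiodinase of liver, Amdhd1 (-5.80), Cyp8b1 (-5.75) of bile acid synthesis, Serpina12 (-5.23), Ugt2b38 (-4.89) and Cyp2f2 (-4.41).

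Of 12 measured Wnt targets in the gene lists fixed in advance, 9 rose and 1 fell (9 and 1 adjusted over the list alone), among them Axin2 (2.77), Sp5 (3.04), Lgr5 (2.40) and Ccnd1 (2.68), the cyclin of G1 phase; the 1 that fell was Lgr4 (-1.59). Their median was 2.13 (adjusted p = 0.00368 against the other named genes, and adjusted p = 0.136 with an estimated correlation). Of 18 pericentral genes 16 rose and 1 fell (16 and 2 adjusted over the list alone), with a median of 2.32 (adjusted p = 6.07e-07, and adjusted p = 0.0381 with an estimated correlation). Of 18 periportal genes 16 fell and none rose (17 and 0 adjusted over the list alone), including Gldc (-3.11), Pigr (-2.64) and Arg1 (-3.52). Their median stood at -2.78 (adjusted p = 3.85e-09, and adjusted p = 0.124 with an estimated correlation). Of 7 urea cycle and amino acid genes 6 fell (7 adjusted over the list alone), with Otc at -2.66. These had a median of -3.53 (adjusted p = 0.000132, and adjusted p = 0.205 with an estimated correlation).

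Cell cycle genes rose together: 21 of 24 rose and 1 fell (21 and 1 adjusted over the list alone), with a median of 2.75 (adjusted p = 7.84e-05, and adjusted p = 0.606 with an estimated correlation). Aurka (2.93), Cdca3 (3.51) and Cdca8 (2.86), which act in mitosis, were among them, and Mcm10 (-2.57) was the 1 that fell. Of 8 stress and p53 genes 6 rose (7 adjusted over the list alone), a list that includes Myc itself, with Ier3 (2.36) and Cdkn1a. Their median was 2.27 (adjusted p = 0.00668, and adjusted p = 0.293 with an estimated correlation). Of 7 genes of fatty acid oxidation 4 rose (5 up and 1 down adjusted over the list alone), including Pdk4 (3.84) and Acot4 (2.57); without Apc replicate 2, Apc replicate 3 or WT replicate 1 the list's adjusted p was 0.0601, 0.0696 and 0.0526. It was 0.0733 with only these groups fitted, 0.0804 and 0.0826 on the quantile normalized scores and the scores as they are, 0.0745 with pseudocount 1, 0.0852 without the low probe sets (mean signal below the median) and 0.0674 for the mean of a gene's probe sets. Their median was 2.57 (adjusted p = 0.048, and adjusted p = 0.586 with an estimated correlation). The 4 measured fetal liver and liver cancer genes rose (4 adjusted over the list alone). Their median stood at 4.22 (adjusted p = 0.0265, and adjusted p = 0.256 with an estimated correlation), and without the low probe sets the list's adjusted p was 0.0801.

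Of 10 genes higher in male than in female liver 7 fell (9 adjusted over the list alone), with C8b (-2.69) and Egfr (-2.73) beside Hsd3b5. These had a median of -2.60 (adjusted p = 4.3e-05, and adjusted p = 0.174 with an estimated correlation). Of 8 genes higher in female liver 7 rose (8 adjusted over the list alone), with Trim24 (2.21) and Atp6v0d2 (2.69). Their median was 2.93 (adjusted p = 0.00133, and adjusted p = 0.291 with an estimated correlation). The labels do not give the sex of the animals. Of 5 red cell genes 3 fell (4 adjusted over the list alone), namely Alas2 (-2.40), Car1 (-1.79) and Klf1 (-1.13); without Apc replicate 2, Apc replicate 3 or WT replicate 3 the list's adjusted p was 0.0524, 0.0551 and 0.0501, and Klf1 was not called with the replicate block on these 2 groups (adjusted p = 0.0524). Their median was -1.13 (adjusted p = 0.0355, and adjusted p = 0.451 with an estimated correlation). In bile acid handling Slco1a4 (2.04) and Abcc2 (1.49), both transporters, rose while Cyp8b1 and the uptake carrier Slc10a1 (-1.49) fell, and the list as a whole was not called (adjusted p = 0.331), but was with each probe set on its own (adjusted p = 0.0444).

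Over all 32115 probe sets tested, 4996 were called in Apc against WT, 2529 up and 2467 down, and 4915 of them had no overlap between the groups; 31.5% of all probe sets had none, where chance gives 10%. With only these groups fitted 3151 were called, and with a replicate block added to that fit 2161, both with fewer degrees of freedom. At least 2-fold changes made up 1277 of the rises and 965 of the falls.

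**Figure D2:**
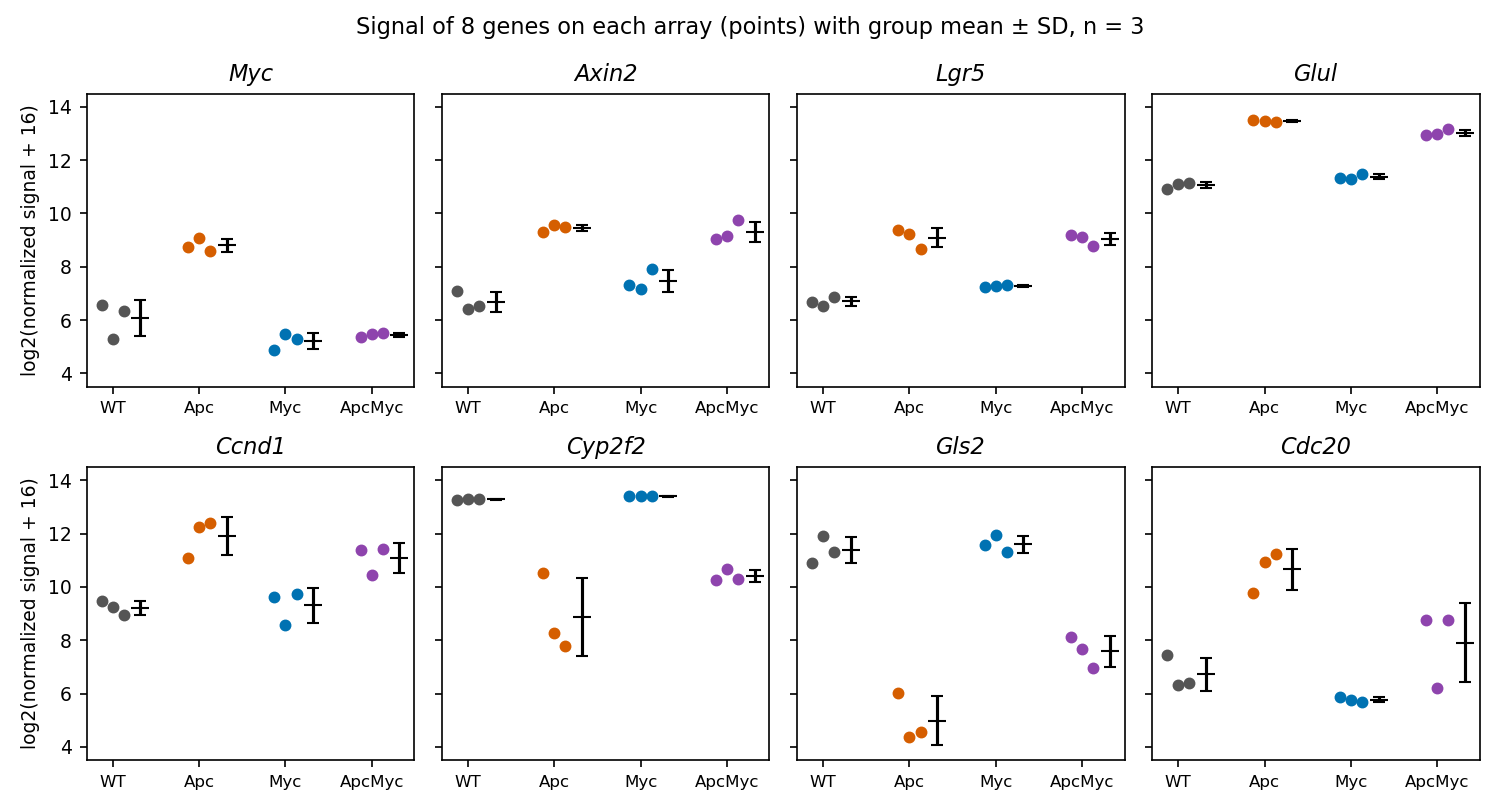
Log2 of the normalized signal plus 16 of Myc, Axin2, Lgr5, Glul, Ccnd1, Cyp2f2, Gls2 and Cdc20 in each array, by group, with the mean and SD (n = 3). Myc stands at 8.80 in Apc and at 5.45 in ApcMyc, while Axin2 stands at 9.45 and 9.32.

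With Myc deleted, Apc loss moved most of the same zonation genes. Myc itself did not pass the test in ApcMyc against Myc, at 5.22 ± 0.299 in Myc and 5.45 ± 0.075 in ApcMyc (n = 3; difference 0.24, adjusted p = 0.645). The labels do not say which part of Myc was removed, so its probes may lie in that part or outside it, and in the latter case the signal checks nothing about the deletion. Glul rose by 1.64 (SE 0.141, adjusted p = 2.48e-05), Axin2 by 1.85 (adjusted p = 0.000584), Lgr5 by 1.77 (adjusted p = 0.000142) and Ccnd1 by 1.77 (adjusted p = 0.011), and Cyp2f2 fell by 3.01 on the log2 scale (adjusted p = 0.0021). The largest rises were Slc22a3 (4.67), Afp (4.31), Mogat2 (4.02), the noncoding RNA Meg3 (listed as Gtl2, 3.79), AW124722 (3.64), D17H6S56E-5 (3.58), Sema3b (3.51), Akr1b7 (3.49), Prom1 (3.39) and Tuba8 (3.38). The largest falls were Hsd3b5 (-5.66), Cyp8b1 (-4.99), Dio1 (-4.24), Sds (-4.05), Gls2 (-4.02), Hal (-3.99), Serpina12 (-3.90), Mup3 (-3.82), Amdhd1 (-3.70) and Igfbp2 (-3.62).

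Of the 12 Wnt targets 10 rose and 1 fell (10 and 1 adjusted over the list alone), and Sp5 (2.17) and Tbx3 (1.36) were among those that rose. Their median stood at 1.57 (adjusted p = 0.0017, and adjusted p = 0.124 with an estimated correlation). Of the 18 pericentral genes 16 rose (16 up and 1 down adjusted over the list alone), such as Rhbg (3.02) and Slc16a10 (2.23), an amino acid carrier. These had a median of 1.71 (adjusted p = 1.93e-06, and adjusted p = 0.0381 with an estimated correlation). Of the 18 periportal genes 17 fell (18 adjusted over the list alone), such as Hsd17b6 (-2.79) and Gldc (-1.99). Their median was -1.81 (adjusted p = 6.37e-08, and adjusted p = 0.136 with an estimated correlation). Of the 7 urea cycle and amino acid genes 6 fell (6 adjusted over the list alone), with Otc at -2.16 and Prodh2 at -1.82. Their median was -2.16 (adjusted p = 0.00117, and adjusted p = 0.256 with an estimated correlation).

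The cell cycle list also shifted up, with 10 of 24 genes up and 1 down (21 and 1 adjusted over the list alone; adjusted p = 0.00912, and adjusted p = 0.667 with an estimated correlation). The number that rose depended on single arrays and on the scale. It was 1, 19 and 5 without ApcMyc replicates 1, 2 and 3, and 3, 2 and 2 without Myc replicates 1, 2 and 3. On either form of the scores and with pseudocount 1 it was 3, and with median scaling or an intensity trend 16. Without the low probe sets the list's adjusted p was 0.0799. Mcm6 (2.54), a subunit of the replicative helicase, had the smallest p among those that rose. Of the 10 male-biased genes 7 fell (8 adjusted over the list alone). Their median stood at -2.08 (adjusted p = 0.00034, and adjusted p = 0.226 with an estimated correlation). Of the 8 female-biased genes 5 rose (5 adjusted over the list alone). These had a median of 2.16 (adjusted p = 0.0127, and adjusted p = 0.451 with an estimated correlation). Of the lists called in Apc against WT, 4 did not pass here, though each had members that did. Of 8 stress and p53 genes 5 rose (5 adjusted over the list alone, list adjusted p = 0.121), 3 on either form of the scores and with pseudocount 1, and of 7 fatty acid oxidation genes 3 rose and 1 fell (3 and 1 adjusted over the list alone, list adjusted p = 0.331). Of 5 red cell genes 4 fell, against 3 in Apc against WT (4 adjusted over the list alone, median -1.06, list adjusted p = 0.0605). Without Myc replicate 2 the number was 2, and the red cell list was called without ApcMyc replicate 3 (adjusted p = 0.0411) and with only these groups fitted (adjusted p = 0.0484). Of 4 fetal liver and liver cancer genes 2 rose (2 adjusted over the list alone, list adjusted p = 0.14), and the list was called with each probe set on its own (adjusted p = 0.0443). In all, 4302 probe sets were called, 2131 up and 2171 down, 4280 of them without overlap; 35.7% of all probe sets had none. Scaling the arrays to a common median signal in place of quantile normalization gave 1759 up and 3511 down, and without Myc replicate 1, 2 or 3 or ApcMyc replicate 1 the count was 2782, 2535, 2648 and 2764.

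Across the 4996 probe sets called in Apc against WT, the differences between ApcMyc and Myc had a slope of 0.54 on those between Apc and WT (jackknife SE 0.0761), and 83.5% had the same sign. A slope over probe sets selected in one comparison leans towards a smaller response in the other. Over the 4302 probe sets called in ApcMyc against Myc it was 0.80. Over the 500 with the largest mean of both effects, a choice that favours probe sets moving the same way in both, it was 0.69. Over all 32115 probe sets it was 0.46, with a correlation of 0.52, and 60.4% had the same sign. Noise in the differences between Apc and WT also lowers a slope, most where many probe sets are unchanged. The 0.46 is therefore not the share of the response kept. Of the rises, 877 were called in both comparisons, where 168 would be if calls were independent, and of the falls 896 against 167. In all, 52 probe sets were called in opposite directions. These slopes are across probe sets, which are not independent replicates.

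**Figure D3:**
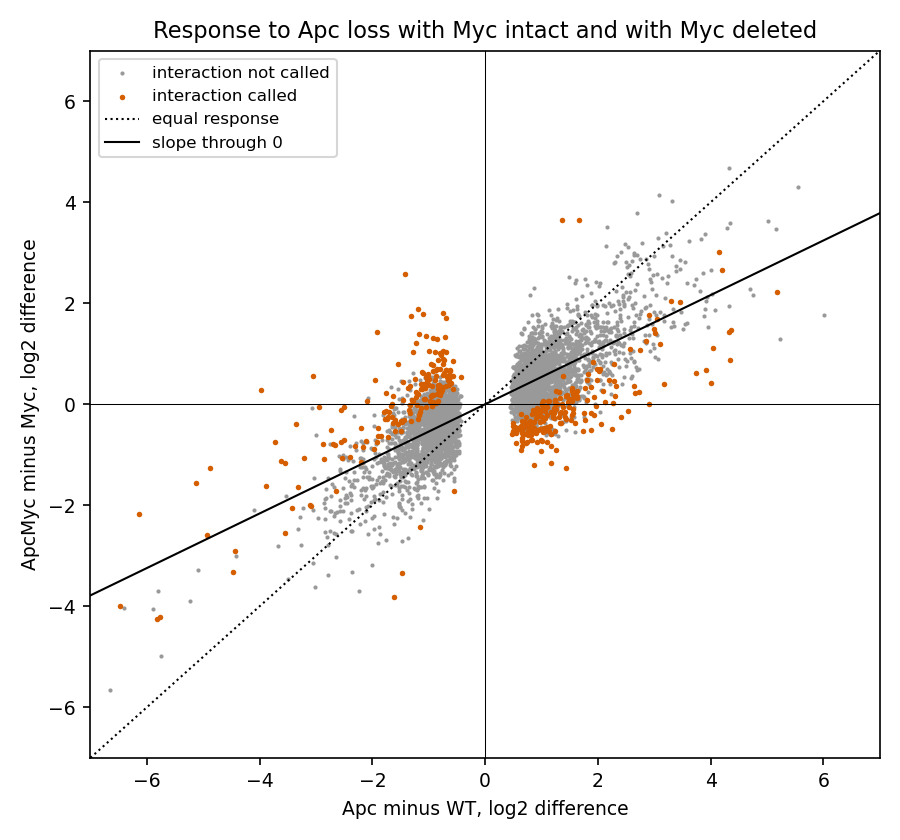
Log2 difference of ApcMyc minus Myc (vertical axis) against that of Apc minus WT (horizontal axis) for the 4996 probe sets called in Apc against WT, with those called in the test of the difference between the responses in orange. The dotted line marks equal responses and the solid line the fitted slope of 0.54.

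The test of the difference between the 2 responses, ApcMyc minus Myc less Apc minus WT, cancels an additive difference between the title styles. Myc itself differed: its rise with Apc loss was smaller by 2.49 on the log2 scale with Myc deleted (-2.49, SE 0.405, adjusted p = 0.0154). Thrsp, a lipid synthesis gene, fell with Apc loss when Myc was intact (-2.95) and stood at -0.06 with Myc deleted (difference of responses 2.89, adjusted p = 0.0116), and Kynu, of tryptophan breakdown, had a difference of 2.50 (adjusted p = 0.00575). The difference of responses was also positive for Celf2 (listed as Cugbp2, 2.60), Ccnt2 (2.52), Ppp4r3a (listed as Smek1, 2.29) and AW124722 (2.28). It was negative for Mme (-2.78), a peptidase, Ap2b1 (-2.28) and Mup3 (-2.22). The probe sets of Ap2b1 were called in opposite directions in ApcMyc against WT. On the scores as they are AW124722 (adjusted p = 0.0546), Mme (0.0716) and Mup3 (0.104) were not called, nor on the quantile normalized scores AW124722 (0.0512) and Mme (0.0679), nor with pseudocount 1 Mme (0.0595). None of the 5 markers passed this test: Glul was at -0.77 (adjusted p = 0.0658), Axin2 -0.92 (adjusted p = 0.188), Lgr5 -0.63 (adjusted p = 0.246), Ccnd1 -0.90 (adjusted p = 0.411) and Cyp2f2 1.41 (adjusted p = 0.31). Other genes with large differences were Ugt2b38 (3.62), Slfn4 (2.51), Hal (2.48), Asap2 (listed as Ddef2, 2.36), Plat (-2.94), Psat1 (-2.68), Clec2h (-2.49), Ddr1 (-2.43) and Ywhag (-2.17). Each of these 9 calls ended when any 1 of several arrays was left out. The highest adjusted p was 0.105 for Ugt2b38 without Myc replicate 1 and 0.0592 for Slfn4 and for Plat without Myc replicate 2. It was 0.091 for Hal without Apc replicate 2, 0.0619 for Asap2 without Myc replicate 3, 0.0648 for Psat1 and 0.0661 for Clec2h without Myc replicate 2. For Ddr1 it was 0.057 without Myc replicate 3, and for Ywhag 0.0627 without Myc replicate 1. None of the 9 was called on the scores as they are, on the quantile normalized scores or with pseudocount 1. Over these 3 scales the highest adjusted p was 0.51 for Clec2h, 0.158 for Psat1, 0.151 for Hal, 0.113 for Ddr1, 0.104 for Ugt2b38, 0.0878 for Slfn4, 0.0862 for Ywhag, 0.081 for Asap2 and 0.0716 for Plat.

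By list, the pericentral genes responded less with Myc deleted (median -0.41, adjusted p = 0.00588, and adjusted p = 0.16 with an estimated correlation), with 3 called lower and none higher (5 and 1 adjusted over the list alone): Slc1a4 (-1.60), Slc1a2 (listed as 2900019G14Rik, -1.42) and Rhbg (-1.13). The list's median was 0.48 in Myc against WT and -0.03 in ApcMyc against Apc, both across the title styles. Rhbg stood at 7.73 in WT, 8.81 in Myc, 11.88 in Apc and 11.83 in ApcMyc. Slc1a4, in contrast, was lower in ApcMyc (7.52) than in Apc (9.63). The periportal genes fell less (median 0.94, adjusted p = 0.000836, and adjusted p = 0.33 with an estimated correlation), with 4 called higher and none lower (10 and 1 adjusted over the list alone): Gldc (1.12), Pigr (0.92), Ftcd (1.06) and Hal. Of these, Slc1a4 alone stayed called whichever array was left out. Of the pericentral genes 1 was called lower without Apc replicate 2, ApcMyc replicate 2, Myc replicate 1, Myc replicate 3 or WT replicate 2, 1 on either form of the scores and with pseudocount 1, and 6 with median scaling. Of the periportal genes none was called higher without Apc replicate 2, ApcMyc replicates 1 or 2, any Myc replicate or WT replicates 2 or 3, nor on the quantile normalized scores or with pseudocount 1. It was 1 without WT replicate 1, on the scores as they are and with median scaling. The highest adjusted p for the others was 0.0727 for Slc1a2 without WT replicate 2, 0.0881 for Rhbg without Myc replicate 2, 0.0831 for Gldc without Myc replicate 1, 0.114 for Pigr without Myc replicate 2 and 0.11 for Ftcd without ApcMyc replicate 2. Over other scales it was 0.0506 for Slc1a4, 0.0631 for Slc1a2, 0.0696 for Rhbg, 0.065 for Gldc, 0.0743 for Pigr and 0.0827 for Ftcd. The cell cycle genes rose less as a list (median -1.24, adjusted p = 0.00539, and adjusted p = 0.667 with an estimated correlation), with no member called alone (0 up and 5 down adjusted over the list alone), among them Aurka at -1.88 (adjusted p = 0.0595) and Hmmr at -2.04 (adjusted p = 0.102). Without Apc replicate 3 the list's adjusted p was 0.0508, and with fry 0.165. Of its members 2 were called lower without ApcMyc replicate 1, and 4 with pseudocount 64. The urea cycle and amino acid list (median 1.71, adjusted p = 0.0421, and adjusted p = 0.516 with an estimated correlation) had 1 member, Hal, called higher (4 adjusted over the list alone). The list's adjusted p was 0.0871 without Apc replicate 2, 0.0677 without Apc replicate 3, 0.0528 without ApcMyc replicate 1, 0.0545 without Myc replicate 2, 0.0528 without Myc replicate 3, 0.0653 without WT replicate 2 and 0.0731 without WT replicate 3. It was 0.0548 on the quantile normalized scores, 0.0835 with pseudocount 64 and 0.0919 without the low probe sets, and the list was not called with pseudocount 1 either. The count of 1 was 3 without Apc replicate 1 or ApcMyc replicate 3 and 0 without any other array, on either form of the scores and with pseudocount 1. Fatty acid oxidation (median -1.31, adjusted p = 0.0128, and adjusted p = 0.516 with an estimated correlation) had Acot4 (-1.48) called lower (0 up and 3 down adjusted over the list alone). The Acot4 call did not hold for the mean of its probe sets (adjusted p = 0.117), and the list's adjusted p was 0.0551 without Apc replicate 3. Stress and p53 (median -0.86, adjusted p = 0.0289, and adjusted p = 0.45 with an estimated correlation) had Myc and Psat1 called lower (0 up and 4 down adjusted over the list alone). Myc is the gene deleted in the Myc and ApcMyc groups, so its lower response may be the deletion itself if its probes lie in the deleted part, which the labels do not give. The list was not tested without Myc. The list's adjusted p was 0.0696 without Apc replicate 3, 0.0676 without Myc replicate 3, 0.0941 on the quantile normalized scores, 0.0769 on the scores as they are and 0.08 with pseudocount 1. In place of 2 members 1 was called without Apc replicate 2, ApcMyc replicate 2 or any Myc replicate, none on these 3 scales and 4 with pseudocount 64.

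In this test 744 probe sets were called, 386 up and 358 down. In 523 the responses had opposite directions, in 146 the response was smaller in the same direction with Myc deleted, and in 75 larger. Opposite directions mostly involve a response that was not called, since in 52 of the 523 both were called. Of the 744, 289 were called in Apc against WT alone and 337 in ApcMyc against Myc alone. The count depended on single arrays: without Apc replicate 2, ApcMyc replicate 1, ApcMyc replicate 2, Myc replicates 1, 2 and 3, WT replicate 2 and WT replicate 3 it was 171, 338, 168, 180, 199, 171, 151 and 336. It also depended on the scale: the deposited scores as they are gave 162, quantile normalized scores 149, pseudocount 1 194, pseudocount 64 1586, an intensity trend 1309, leaving out the low probe sets 1398 and median scaling 1207, of which 402 were up and 805 down. The Myc call itself missed the threshold on the scores as they are (adjusted p = 0.0806), on the quantile normalized scores (0.0736) and with a pseudocount of 1 (0.0669). Thrsp, Celf2, Ccnt2, Kynu, Ppp4r3a and Ap2b1 stayed called under every alternative and without any 1 array.

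**Figure D4:**
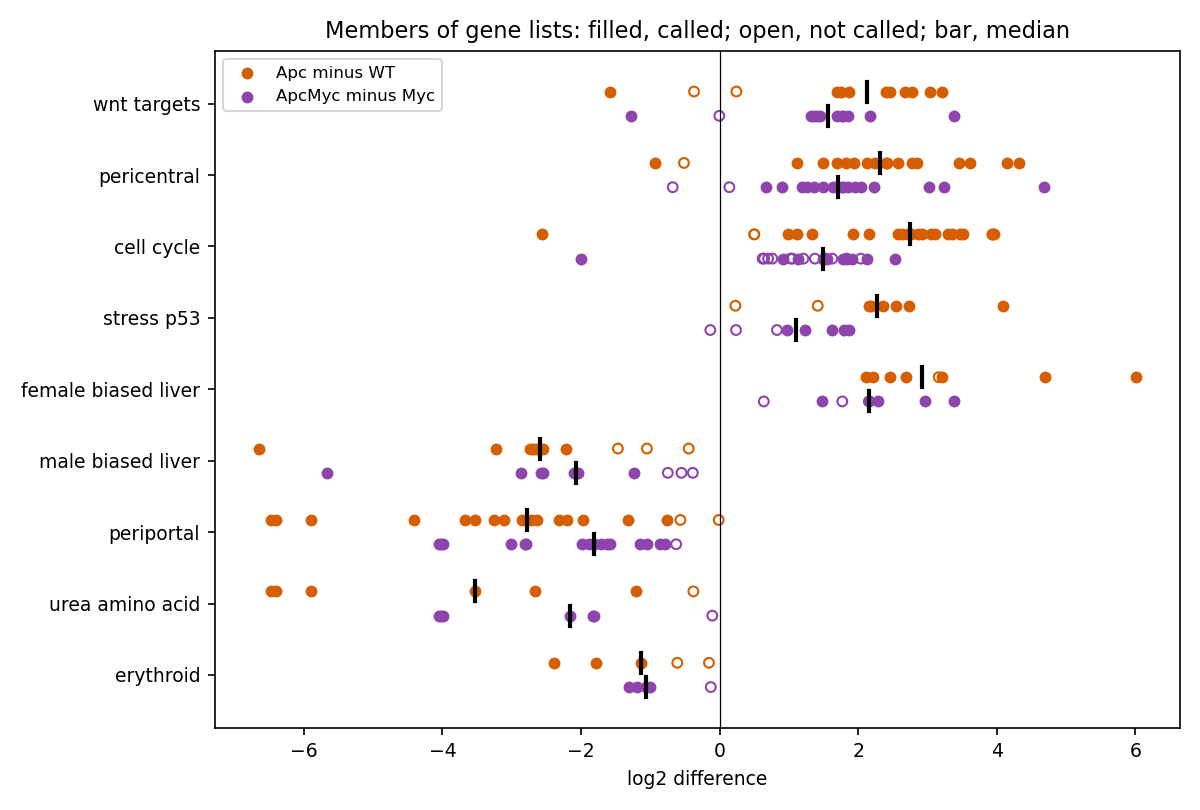
Log2 differences of the measured members of 9 gene lists in Apc against WT (orange) and in ApcMyc against Myc (purple), 1 point per gene, filled where called, with a bar at the median. The medians are 2.13 and 1.57 for Wnt targets, 2.32 and 1.71 for pericentral and -2.78 and -1.81 for periportal genes.

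In Myc against WT, which crosses the title styles, Myc itself was at -0.85 and was not called (5.22 ± 0.299 against 6.07 ± 0.678, n = 3; adjusted p = 0.0833). None of the 5 Wnt and zonation markers reported in every comparison passed: Glul 0.32 (adjusted p = 0.178), Axin2 0.79 (adjusted p = 0.0706), Lgr5 0.57 (adjusted p = 0.0885), Cyp2f2 0.13 (adjusted p = 0.91) and Ccnd1 0.09 (adjusted p = 0.918). Clec2h rose by 2.95 (adjusted p = 0.000636), AW011956 by 2.59, Sema3f by 2.49, Rusc2 by 2.00 and Atox1, a copper chaperone, by 1.94. Pctp and a probe set whose symbol is listed in the form of a calendar date were also among the largest rises. Prdx4 (-2.53, adjusted p = 0.000216), an antioxidant enzyme, fell, as did Ugt2b38 (-3.30), the noncoding RNA Malat1 (-2.34), Hsd3b5 (-2.21), Nisch (-2.17), Ttyh2 (-2.08), Dpys (-2.06) and Mthfd1 (-1.97). On the scores as they are, on the quantile normalized scores and with a pseudocount of 1 Dpys was not called (adjusted p between 0.051 and 0.0729). The calls of Cyp2c39 (4.33, adjusted p = 0.0456), Cyp4a14 (3.65), Klf12 (-1.95) and Polr3k (-2.13) were not stable. With only these groups fitted the adjusted p of Cyp2c39 was 0.0667, on the quantile normalized scores 0.0598, and with pseudocounts 1 and 64 it was 0.058 and 0.0629. That of Klf12 was 0.215 for the mean of its probe sets and 0.0733 to 0.0795 on either form of the scores and with pseudocount 1. The adjusted p of Cyp2c39 was 0.152, 0.157, 0.103, 0.122 and 0.0688 without Myc replicates 2 and 3 and WT replicates 1, 2 and 3. That of Cyp4a14 was 0.0996, 0.0944, 0.069 and 0.0855 without Myc replicates 1 and 3 and WT replicates 2 and 3. That of Klf12 was 0.0577 to 0.117 without any 1 of the 6 arrays, and that of Polr3k 0.057 and 0.054 without Myc replicate 2 and WT replicate 2.

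Of the 10 male-biased genes 3 fell (3 adjusted over the list alone), including Elovl3 (-1.93). Their median was -0.66 (adjusted p = 0.0339, and adjusted p = 0.515 with an estimated correlation). Of the 8 female-biased genes 4 rose (6 adjusted over the list alone), including Trim24 (1.08), and without Myc replicates 1 or 3 or WT replicates 2 or 3 the number was 2, 1, 2 and 1. Their median was 1.40 (adjusted p = 0.0476, and adjusted p = 0.516 with an estimated correlation). Without Myc replicate 3 or WT replicate 3 the adjusted p of the male-biased list was 0.0528 and 0.0501. Without Myc replicate 1, Myc replicate 3, WT replicate 1 or WT replicate 3 that of the female-biased list was 0.0506, 0.0543, 0.0739 and 0.0514. Neither was called on the quantile normalized scores (adjusted p = 0.0548 for both), without the low probe sets (0.0852 and 0.0799) or with pseudocount 1, and the female-biased list also not with pseudocount 64 (0.0837) or on the scores as they are (0.0503). Of the 18 pericentral genes 5 rose and 2 fell (8 and 3 adjusted over the list alone, median 0.48), and of the 24 cell cycle genes 1 rose (0 adjusted over the list alone). Neither list was called (adjusted p = 0.219 for the pericentral list). Of the pericentral genes 4, 4 and 2 rose without Myc replicates 1, 2 and 3 and 4, 3 and 3 without WT replicates 1, 2 and 3, with 0, 0, 1, 0, 0 and 1 falling. No cell cycle gene was called without any 1 array other than Myc replicate 3, and 2 rose on the scores as they are. Of 32115 probe sets 2925 were called, 1302 up and 1623 down, 2920 of them without overlap; 33.3% of all had none. Median scaling gave 2251 up and 1523 down, and without Myc replicate 1, 2 or 3 or WT replicate 2 or 3 the count was 1537, 1248, 1306, 1442 and 1517.

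Between ApcMyc and Apc, again across the title styles, Myc was lower in ApcMyc by 3.35 on the log2 scale (-3.35, 5.45 ± 0.075 against 8.80 ± 0.258, n = 3; adjusted p = 5.08e-05). Axin2 (-0.13, adjusted p = 0.758), Lgr5 (-0.05, adjusted p = 0.88) and Ccnd1 (-0.81, adjusted p = 0.167) did not pass the test. Of 24 cell cycle genes 10 fell, 1 rose and 13 were not called (12 fell and 1 rose adjusted over the list alone). Among those that fell were Cdc20 (-2.75), Ube2c (-2.62), Hmmr (-2.41) and Cdca3 (-2.27). On the quantile normalized scores 6 fell, on the scores as they are 5, and 7 with pseudocount 1, with none rising on these 3 scales. The list's shift stayed called in 7 of 18 alternatives. Without Apc replicate 2, Apc replicate 3 or ApcMyc replicate 2 the list's adjusted p was 0.128, 0.13 and 0.0741. It was 0.117 with fry, 0.0637 with only these groups fitted, 0.1 and 0.0914 on the quantile normalized scores and the scores as they are, 0.0799 without the low probe sets, 0.0902 with pseudocount 1 and 0.0564 for the mean of a gene's probe sets. Their median stood at -0.98 (adjusted p = 0.0442, and adjusted p = 0.725 with an estimated correlation). The lipid gene Thrsp (3.59), Pik3cd (3.53), Gdpd3 (3.16), the macrophage receptor Marco (2.71), Gbp2b (listed as Gbp1, 2.70), Gls2 (2.60), Celf2 (2.45), Fen1 (2.44), Hal (2.41) and Kynu (2.37) had the largest rises. On the scores as they are Gdpd3 (adjusted p = 0.0608) and Hmmr (adjusted p = 0.0524) were not called, nor Gdpd3 on the quantile normalized scores (0.0617). Ly6d (-3.96), Ddr1 (-3.31), Tlcd4 (listed as Tmem56, -3.00), Cox6b2 (-2.98), Prdx4 (-2.85), Plat (-2.79) and Mup3 (-2.74) were among the other large falls. Glul was lower (-0.45, adjusted p = 0.0399) and Cyp2f2 higher (1.53, adjusted p = 0.0471), and both calls ended without single arrays. For Glul the adjusted p was 0.0784, 0.0894, 0.0666, 0.108 and 0.104 without Apc replicates 1, 2 and 3 and ApcMyc replicates 1 and 2. For Cyp2f2 it was 0.156, 0.162, 0.0825, 0.127 and 0.0877 without Apc replicates 2 and 3 and ApcMyc replicates 1, 2 and 3. With only these groups fitted it was 0.11 for Glul and 0.12 for Cyp2f2, and Cyp2f2 was at 0.0743 with median scaling, 0.116 and 0.0874 on the scores as they are and quantile normalized, and 0.0831 with pseudocount 1.

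Endothelial genes rose as a list, 6 of 8 (6 adjusted over the list alone), with Kdr at 1.85, Mrc1 at 1.53 and Flt4 at 1.43; without Apc replicate 3 the list's adjusted p was 0.0551, and without the low probe sets 0.0555. These had a median of 1.21 (adjusted p = 0.0235, and adjusted p = 0.606 with an estimated correlation). Of 6 named macrophage genes 5 rose, such as Timd4 (2.11), and all 4 named T and NK cell genes rose, such as Ccl5 (1.68), as many as adjusted over the list alone, while neither list was called as a whole (adjusted p = 0.0578 and adjusted p = 0.0771). Among the 4, Nkg7 was not called without Apc replicate 2 (adjusted p = 0.0897), ApcMyc replicate 1 (0.0629) or ApcMyc replicate 3 (0.0619), on the scores as they are (0.0646), on the quantile normalized scores (0.0685) or with pseudocount 1 (0.06). Without ApcMyc replicate 2 both lists were called (adjusted p = 0.0356 and adjusted p = 0.0445), and the macrophage list also with only these groups fitted (0.0482), with median scaling (0.0489) and with each probe set on its own (0.0311). Only named genes count here, of lists that hold 21 macrophage, 20 T and NK cell and 25 endothelial genes. Since most named genes were chosen for a change in ApcMyc against WT, which shares the ApcMyc arrays, these counts say little by themselves. These differences of cell type markers stood beside those of the hepatocyte genes above. Over all probe sets 6702 were called, 3375 up and 3327 down, 6532 of them without overlap; 36.4% of all had none.

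Mice lacking both genes were last set against WT. Myc was at -0.61 and was not called (5.45 ± 0.075 against 6.07 ± 0.678, n = 3; adjusted p = 0.14). Glul (1.96, adjusted p = 4.05e-06), Axin2 (2.64), Lgr5 (2.35) and Ccnd1 (1.86, adjusted p = 0.00467) rose and Cyp2f2 (-2.88) fell. Among the largest rises were Cyp2c39 (5.88), Cyp4a14 (5.42), Slc22a3 (5.16), Afp (4.61), Akr1b7 (4.28), Mogat2 (4.26), Rhbg (4.10), Acot3 (4.02) and Rcan2 (3.95). The largest falls were Hsd3b5 (-7.87, adjusted p = 1.18e-07), Cyp8b1 (-6.13), Serpina12 (-5.57), Dio1 (-5.22), Ugt2b38 (-4.56), Mup3 (-4.35), Hal (-4.06), Amdhd1 (-4.06), Elovl3 (-3.98) and Aqp8 (-3.93). Of the 2176 named genes 1022 rose and 820 fell here, and most were named for a change in this same comparison, so counts close to a whole list say little by themselves. The 18 measured of 41 periportal genes fell (18 adjusted over the list alone). Their median was -2.33 (adjusted p = 9.42e-06, and adjusted p = 0.215 with an estimated correlation). Of 18 pericentral genes 16 rose and 2 fell (16 and 2 adjusted over the list alone), 1 without any 1 of the 6 arrays. Their median was 2.07 (adjusted p = 0.000861, and adjusted p = 0.124 with an estimated correlation). Of the Wnt targets 10 rose and 1 fell (10 and 1 adjusted over the list alone, median 1.87, adjusted p = 0.0339, and adjusted p = 0.242 with an estimated correlation). On the quantile normalized scores (adjusted p = 0.0543), on the scores as they are (0.0554) and with pseudocount 1 this list was not called. The 7 measured urea cycle and amino acid genes fell (7 adjusted over the list alone, median -2.17, adjusted p = 0.00539, and adjusted p = 0.33 with an estimated correlation). The 10 measured male-biased genes fell (10 adjusted over the list alone, median -2.37, adjusted p = 0.000861, and adjusted p = 0.256 with an estimated correlation). The 8 measured female-biased genes rose (8 adjusted over the list alone, median 3.67, adjusted p = 0.0142, and adjusted p = 0.452 with an estimated correlation). The cell cycle list was not called (14 up and 1 down, 18 and 1 adjusted over the list alone, median 1.34, adjusted p = 0.0691). Without ApcMyc replicate 2 it was called (22 up, adjusted p = 0.00306), as it was with each probe set on its own (adjusted p = 0.0444). Markers of other cell types also differed in this comparison. Of 6 named macrophage genes 5 rose (6 adjusted over the list alone), of 8 named endothelial genes 6 (6 adjusted over the list alone) and of 4 named T and NK cell genes 4 (4 adjusted over the list alone), while the 5 named red cell genes fell (5 adjusted over the list alone). None of these lists was called (adjusted p = 0.233, 0.149, 0.315 and 0.0605), though the red cell list was without WT replicate 1 (adjusted p = 0.0492). The macrophage count was 3 without ApcMyc replicate 1 or 3, with only these groups fitted, on either form of the scores and with pseudocount 1, and 2 without WT replicate 2 or 3. The T and NK cell count was 2 without ApcMyc replicate 3 or WT replicate 2 or 3, and the red cell count 3 without ApcMyc replicate 2 or WT replicate 2 or 3. Over all probe sets 7954 were called, 3915 up and 4039 down, 7773 of them without overlap; 39.9% of all had none.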

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

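The comparison of the responses was planned, while the tests of explanations and the count over other assignments of the residuals were chosen after the results were seen.

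The response to Apc loss differed with Myc deleted in 744 probe sets by a test of the difference itself, and the same test called the named genes and 6 gene lists below, none of the lists with an estimated correlation (adjusted p from 0.16 to 0.667). Of 100 assignments of the arrays' residuals around a fit with no difference of responses 1, the real one, gave as many calls, and the highest of the others gave 54. This share holds only if the arrays are independent samples, which the labels do not state. The calls also depended on single arrays and on the scale, so chance is not excluded. Fewer recombined cells in ApcMyc livers would shrink responses, yet 51.3% of the called probe sets had a larger response with Myc deleted that was itself called. This argues against it as the whole cause, unless a signal scale that differs between the title styles made these responses larger. That the larger response was itself called adds little, since it was in 382 of the 387 with a larger response. Of the 744, though, 75 were larger in the same direction. The 6 called list shifts all ran towards a smaller response, the direction that fewer recombined cells would give, so a part for this cause stays open. For the pericentral list, though, the median was -0.03 in ApcMyc against Apc and 0.48 in Myc against WT, both across the title styles. Its smaller response therefore went more with a higher level in Myc than in WT. A signal scale that differs with the brighter arrays of the Myc-deleted groups stays open: all 744 kept their sign on 5 other scales, and 644 stayed called with median scaling, 713 with pseudocount 64, 191 with pseudocount 1, 152 on the scores as they are and 143 on the quantile normalized scores. A dependence of these genes on Myc may account for the rest and was not tested on its own.

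Cell cycle genes rose less with Myc deleted as a list (median -1.24, adjusted p = 0.00539, and adjusted p = 0.667 with an estimated correlation), and no member passed the test alone (5 did, adjusted over the list alone). Over the 21 that rose in Apc against WT, a median of 34.6% of the rise in signal remained (11.3% to 113%), so fewer recombined cells would need 65.4% of cells to be unrecombined. The 10 largest falls in ApcMyc against Myc left a median of 6.11% of the Myc signal (0.247% to 9.05%, the lowest for Hsd3b5, which lay near the floor). This argues against a share as large as 65.4% if unrecombined cells kept that signal and the falls occurred within recombined cells. These genes were chosen for the size of their falls, and a smaller share is not excluded. Hal, Gls2 and Sds fell less than in Apc against WT, the direction that fewer recombined cells would give, while Mup3 fell more. The list's shift stayed called on the same 5 other scales, and was not called with fry (adjusted p = 0.165) or without Apc replicate 3 (adjusted p = 0.0508). A need for Myc stays open and was not tested on its own.

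The other differences of the responses between livers with and without Myc are given as values. The pericentral list had a median of -0.41, the periportal list 0.94, the urea cycle and amino acid list 1.71, the fatty acid oxidation list -1.31 and the stress and p53 list, which holds the deleted gene Myc, -0.86. The difference of responses was positive for Ugt2b38 at 3.62, Thrsp at 2.89, Celf2 at 2.60, Ccnt2 at 2.52, Slfn4 at 2.51, Kynu at 2.50, Hal at 2.48, Asap2 at 2.36, Ppp4r3a at 2.29, AW124722 at 2.28, Gldc at 1.12, Ces2a at 1.06, Ftcd at 1.06 and Pigr at 0.92. It was negative for Plat at -2.94, Mme at -2.78, Psat1 at -2.68, Myc at -2.49, Clec2h at -2.49, Ddr1 at -2.43, Ap2b1 at -2.28, Mup3 at -2.22, Ywhag at -2.17, Slc1a4 at -1.60, Acot4 at -1.48, Slc1a2 at -1.42 and Rhbg at -1.13. These values are not differences of level. Ugt2b38 was lower in Myc than in WT (-3.30), at 4.58 in Apc and 4.91 in ApcMyc, and Clec2h was higher in Myc than in WT (2.95). The adjusted p of Ces2a was highest without Myc replicate 2, at 0.0648; it was 0.0513 on the quantile normalized scores and 0.0501 with pseudocount 1. The other calls that ended without 1 array or on another scale are given in the report.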

How the results depend on the processing

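The alternatives on the deposited scores as they are, those of the controls and the slope with median scaling and other pseudocounts were added after the data were seen; the others were planned. No value of a named gene and no list shift reversed, but with median scaling the balance of calls turned in Myc against WT, from 1302 up and 1623 down to 2251 and 1523, and went from 386 and 358 to 402 and 805 in the difference of the responses. The count for this difference moved from 744 to 1309 with an intensity trend, 149 on quantile normalized scores, 162 on the scores as they are, 1207 with median scaling, 1398 without the probe sets below the median mean (fewer tested), 194 with pseudocount 1 and 1586 with pseudocount 64. Its 17 list members became 30, 4 and 7 on the first 3 of these, 4 with pseudocount 1, 37 with pseudocount 64 and 32 without the low probe sets. Apc against WT gave 3151 calls with only those groups fitted and 2161 with a replicate block added to that fit (fewer degrees of freedom in both). List shifts went from 34 to 2 with an estimated correlation and 94 with fry, which does not compare with other genes; the slope of 0.54 became 0.80 and 0.69 over other probe sets. Overlap with the authors' list for ApcMyc against WT was 92.4% for the stricter list and 86.7% for the looser. The control cre passed at 0.23 on the scores and 0.44 with median scaling, and bioD, at 0.30 (adjusted p = 0.0548) with median scaling, did not. Except where a setting's construction is named, the cause was not tested.

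Leaving out 1 array gave 3333 to 4685 calls for Apc against WT, 2535 to 3748 for ApcMyc against Myc, 1248 to 2530 for Myc against WT, 4589 to 5812 for ApcMyc against Apc, 6009 to 6954 for ApcMyc against WT and 151 to 921 for the difference of responses. List members called were 120 to 138, 89 to 111, 22 to 47, 57 to 69, 141 to 165 and 5 to 19 in the same order, and the slope 0.502 to 0.583. List shifts were 11 to 28 over the comparisons that hold the array, 3 or 4 of the 6, where 15 to 25 of the 34 were called with all arrays; the largest move was from 19 to 11 without Apc replicate 3.

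Of 412 called values of named genes, 339 kept their call under every alternative fit and 337 without any 1 array; of 34 list shifts 2 and 24 did. The covariate for Y-linked genes was not run, as none is named, nor a block for title style, which no fit can separate from Myc deletion. Low signal limits calls: the floor and the added 16 compress folds of dim genes.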

Other observations

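The comparisons of the poly-A, 18S and transferrin receptor controls between title styles, the shares kept by cell cycle genes and the counts over other splits of the arrays were chosen after the results were seen.

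As a share of the rise in signal in Apc against WT, the rise in ApcMyc against Myc was 113% for Rrm1, 113% for Mcm3, 86.2% for Chek1, 83.3% for Mcm5, 82.7% for Mcm6, 80.5% for Mcm4 and 78.0% for Mcm2, of the 21 cell cycle genes that rose in the former. The other 14 lay between 11.3% for Hmmr and 43.8% for Ccna2, with Cdk1 at 42.8%, Cdca8 at 38.4%, Bub1 at 34.6%, Plk1 at 25.8%, Aurka at 17.2% and Cdc20 at 15.6%. Mcm10 fell in both comparisons (-2.57 and -2.01). This order was seen in the values, and no difference between groups of these genes was tested.

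Other lists were measured without a called shift in Apc against WT or ApcMyc against Myc. The list of ribosome biogenesis and Myc targets holds 64 genes, of which only 4 are named, so it says little about Myc targets as a whole. Of these 4 genes 2 rose in Apc against WT (2 adjusted over the list alone, Ncl at 0.96 among them), and 1 without Apc replicate 2 or 3 or WT replicate 2 or 3. In ApcMyc against Myc Ncl (0.76) and Ddx18 (-0.65) were called (1 and 1 adjusted over the list alone), neither stably: without ApcMyc replicate 1 or 2 or Myc replicate 2 or 3 none of the 4 was called. Of 4 cholesterol synthesis genes 2 and 3 rose (2 and 3 adjusted over the list alone), with Hsd17b7 at 1.41 in ApcMyc against Myc; in Apc against WT none rose without Apc replicate 2 or WT replicate 3, and 1 without Apc replicate 3 or WT replicate 1. Of 5 lipogenesis genes 4 fell and 1 rose in Apc against WT (4 and 1 adjusted over the list alone, median -1.59, adjusted p = 0.0605), Srebf1 (-2.18) among those that fell. The 1 did not rise without Apc replicate 2 or 3 or WT replicate 2 or 3, and the list was called without WT replicate 1 (adjusted p = 0.0467) and with each probe set on its own (adjusted p = 0.0443). None of these 5 rose and 3 fell in ApcMyc against Myc (0 and 3 adjusted over the list alone). Among the 3, the calls of Agpat2 and Srebf1 ended without some single array. Of 6 targets of the aryl hydrocarbon receptor, through which the inducer acts, 2 rose in Apc against WT (5 adjusted over the list alone), Nqo1 at 2.16, and 4 without Apc replicate 3 or WT replicate 1 or with an intensity trend; the list was called with each probe set on its own (adjusted p = 0.0443). In ApcMyc against Myc 2 rose (2 adjusted over the list alone), Nqo1 and Xdh, and in ApcMyc against WT all 6 (6 adjusted over the list alone, median 2.91). Without ApcMyc replicate 2 neither Nqo1 (adjusted p = 0.052) nor Xdh (adjusted p = 0.0731) was called in ApcMyc against Myc, and 1 gene was without ApcMyc replicate 1 or 3, with only these groups fitted, on either form of the scores, with median scaling and with pseudocount 1. Of 13 genes of foreign compound metabolism 9 rose and 4 fell in Apc against WT (9 and 4 adjusted over the list alone), Gstm2 at 2.75 and Ces2a (listed as Ces6) at -3.08. The same list had 6 up and 3 down in ApcMyc against Myc (9 and 3 adjusted over the list alone). Of 6 acute phase genes 4 fell in both (4 and 4 adjusted over the list alone, with 1 rising in Apc against WT), with Apcs at -1.75 and -2.69. Of 6 clock genes 2 rose and 3 fell in Apc against WT (2 and 3 adjusted over the list alone), Usp2 at 1.68 and Dbp at -2.78. Only 1 of these rose and none fell in ApcMyc against Myc (1 and 3 adjusted over the list alone). Of 5 genes of glucose metabolism 2 rose and 2 fell in Apc against WT (3 and 2 adjusted over the list alone), and 1 rose without Apc replicate 2 or 3 or WT replicate 3. It was 1 up and 2 down in ApcMyc against Myc (2 and 2 adjusted over the list alone). Neither the neutrophil nor the stellate cell list was called, and the interferon, B cell, bile duct, pancreas and gut and Y-linked lists had too few named members for a test.

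The arrays with Myc deleted differed from those with Myc intact in control probe sets. The poly-A controls added at labelling were higher in WT and Apc arrays. The log2 differences were 3.88 for dap, 1.29 for lys, 1.65 for phe and 1.97 for thr. Each had an exact two-sided permutation p of 0.00216, the smallest such a test can give (adjusted p = 0.0052). 18S rRNA was higher by 3.04 with the same p. The poly-A controls lay between 4.19 and 4.71 in every Myc and ApcMyc array, near the lowest value the added constant allows. The sizes of their differences are therefore compressed and do not measure amounts. The hybridization controls bioB (0.03), bioC (0.10) and cre (0.05) did not pass, bioD did (0.20, adjusted p = 0.0223), the 3' minus 5' difference was -0.33 for Gapdh (adjusted p = 0.0087) and -0.67 for the transferrin receptor (adjusted p = 0.0357), and for Actb 0.08 (exact p = 0.513). A labelling batch may therefore add to every difference across the title styles, and it cannot be told apart from Myc deletion there, since each style holds only one state of Myc; the comparisons within a style do not cross it.

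For comparisons of 3 arrays against 3, 10 splits are too few for a share under 0.05, the smallest being 0.1. In each, 1 split, the real one, gave as many calls. The real counts were 4996, 4302, 2925, 6702 and 7954 for Apc against WT, ApcMyc against Myc, Myc against WT, ApcMyc against Apc and ApcMyc against WT, and the highest of the other splits gave 0, 0, 4, 9 and 0.

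Markers of other cell types also differed across the title styles. Of 6 named macrophage genes 3 were called higher in Myc against WT (4 adjusted over the list alone, list adjusted p = 0.0676), and of 8 named endothelial genes 4 (6 adjusted over the list alone, list adjusted p = 0.052). Without Myc replicate 1 or 3 or WT replicate 2 or 3, or with only these groups fitted, 1 macrophage gene was called higher. Of the endothelial genes none was without WT replicate 2 or 3 and 1 without Myc replicate 2 or 3. Without WT replicate 1 both lists were called (adjusted p = 0.0218 and adjusted p = 0.00929), the macrophage list also without Myc replicate 2 (adjusted p = 0.0277). The endothelial list was called with median scaling (adjusted p = 0.0495), for the mean of a gene's probe sets (0.0422) and with each probe set on its own (0.0311). The differences of Myc minus WT and of ApcMyc minus Apc, which share no arrays, had a correlation of 0.41 across probe sets, which are not independent replicates; 674 rose in both, where 137 would by independence, 716 fell in both, where 168 would, and 60 were called in opposite directions.

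In the SAM lists the authors deposited, the numerators equal differences of mean scores that leave out replicate 1 of the first group, to within 1.96e-07, and the column of gene names holds that array's scores. With all arrays the numerators differ by up to 0.965, and none changes sign. Control probe sets make up 10 of 26 entries of the stricter and 14 of 140 of the looser list of ApcMyc against Apc, and 13 of 105 and 24 of 2871 for ApcMyc against WT, all lower in ApcMyc. Of the probe sets in the looser lists that are not controls, 231 of 250, 107 of 126 and 2467 of 2847 were called here with the same sign in Apc against WT, ApcMyc against Apc and ApcMyc against WT.

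Among 269 genes with 2 or more named probe sets, all probe sets had the same call for 210 in Apc against WT and 187 in ApcMyc against Myc. Probe sets called in opposite directions occurred for Znrf2 in the former, for Rora and Snrnp48 in the latter, for Bcl7c and Ptbp3 in Myc against WT, and for 8 and 13 genes in ApcMyc against Apc, Otc among them, and in ApcMyc against WT.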
